A study of Mus musculus with 6 samples.

How the data were processed

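RNA-seq libraries of sorted mouse subventricular zone cells were analysed, 6 in all and 3 per genotype, on a mixed C57BL/6, Sv/129 and FVB/N background. Per the labels' protocols, mice aged 6 to 10 weeks received tamoxifen by gavage at 200 mg/kg per day for 5 days. Tissue was taken 10 days after the last dose, and several mice were pooled to reach at least 200000 reporter-positive cells per sample. At least 35 ng of total RNA went into SMART-Seq v4 cDNA synthesis and Nextera XT library preparation. The design text calls the 3 samples of a genotype biological replicates. Pooling mice within a sample averages over animals, so the spread between libraries is that of pools.

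Alignment and counting used HISAT2 and featureCounts from Subread on GRCm38, and DESeq2 for the comparison, per the submitters' processing notes, in which no versions are given. The deposited per-library values are a normalized signal: the authors divided the read counts of each gene by 1 size factor per library. The mean over libraries in the same table is also a signal made by the authors. The authors' log2 fold change and its standard error compare knockout with heterozygous libraries, and the Wald statistic and test weight deposited beside them are scores without a fixed range. The authors' p-value and adjusted p-value columns come with those weights, per the file headers. Every value above 0 was a whole multiple of 1 step per library (100% within 0.001 reads), so whole reads and depth could be recovered for the 6 libraries. The step lies within 1% of 1 for heterozygous A and C.

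The design fixed beforehand assumed raw counts and named edgeR's quasi-likelihood test, with limma as the main test if values were normalized and whole reads recoverable, which was the case. The main test was therefore limma 3.58.1 with a mean-variance trend in R 4.3.3 on log2(value + 1), for 18227 of 55487 rows with a mean of at least 10. It was two-sided, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which shrinks ratios of low values. As differences of mean logs they can also exceed the edgeR values where single libraries are at 0, such as -4.91 against -2.82 for Kcnf1. edgeR 4.0.16 on the recovered reads called 2921 genes, 2691 of them shared with limma. The authors' deposited table called 4514 genes at adjusted p under 0.05, including 2866 of the 2883 called here, all 2866 in the same direction. Coordinates came from GENCODE M21 on GRCm38, which held 18212 of the tested gene IDs. Coordinates of single genes are given for the targeted genes.

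The 38 gene lists, covering cell cycle, cell state, signalling, metabolism, stress and other cell types, were fixed before the data were examined, as were the tests and the rule for naming genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the 38 lists, and again with an estimated correlation, under which 0 lists passed, 0 had an unadjusted p under 0.05 and the lowest adjusted p was 0.581. With fry, which asks only whether a list's genes move on balance in 1 direction, 6 lists passed. These were the E2F family, pocket protein and kinase, G1/S, mitosis, activated stem cell and neuroblast lists, all downward (fry adjusted p of 0.0202 to 0.0474). No upward list passed fry, with adjusted p = 0.105 for the quiescent and 0.112 for the ependymal list. Named genes were E2f1 and E2f3; among called genes with a mean of at least 50, a gene name and separated groups, the 8 largest increases and 8 largest decreases and the 3 higher and 3 lower with the smallest p; and up to 3 called members of each list, or the member with the smallest p where none was called. E2f4, E2f5, E2f6, E2f8, Tfdp1, Tfdp2, Ccnd1, Rgcc and Egfr in the results, and the genes singled out in the closing section, were added after their values were seen. Some genes under the naming rule are left out of the text because they are withheld for evaluation.

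Methods were tested on simulated data made from the real means, library sizes and dispersions, with 200 changed genes. Among 18062 genes tested in that simulation of knockout against heterozygous libraries, limma recovered 14% of 2-fold and 77% of 4-fold changes with 1.09% false calls. DESeq2 1.42.0 had 31.6% false calls among its 187 in the same simulation of 30734 genes. DESeq2 also tested genes of low mean that limma left out, and genes outside edgeR's filter were simulated with the median dispersion. The share of false calls depends on how many genes change. Many more genes were called in the real data, so neither share carries over to the calls there, including the authors' calls. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 46.9), so each counted as 1 sample. Alternatives covered normalization, filters, tests, pseudocounts, thresholds, a replicate block and each library left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.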

Results

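RNA was sequenced from cells of the adult mouse subventricular zone, the neurogenic niche along the lateral ventricles. Cells carrying a yellow fluorescent reporter switched on by tamoxifen-inducible Cre under the Nestin promoter, which is active in neural stem cells, were sorted together with their marked descendants. The genotypes compared were heterozygous and knockout, with 3 pooled-mouse libraries each. The heterozygous group had 1 working allele of E2f1 and 1 floxed allele of E2f3, and the knockout group was labelled as null for both E2f1 alleles and floxed for both E2f3 alleles. The E2f1 allele is a germline null, so E2f1 was lost before tamoxifen and in all cells. Floxed E2f3 is meant to be recombined only in Nestin-expressing cells after tamoxifen. Both genes differ between the groups, so the comparison cannot separate their effects or the times of their loss. The series title names the question, which is how activator E2F factors shape the expression signatures of quiescent and activated adult neural stem cells. Reads assigned to genes ranged from 19798675 (knockout A) to 25982361 (knockout B), and 22973 to 25362 genes had at least 1 read. Correlations of log2 values were 0.909 to 0.954 in the 6 pairs of libraries within a genotype and 0.852 to 0.944 in the 9 pairs between genotypes. Knockout C correlated less with knockout A (0.909) than with heterozygous A, B and C (0.929, 0.913 and 0.944). Its correlation with knockout B was 0.954. The first principal component held 51.5% of the variance and separated the genotypes, with heterozygous scores of -65.7, -99.3 and -37.3 and knockout scores of 111.6, 73.2 and 17.5. The knockout scores had the same order of libraries as the ependymal and endothelial levels given below.

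The targeted genes were examined first. E2f1 (ENSMUSG00000027490, GRCm38 chromosome 2, 154559407 to 154569892, minus strand) fell from 1190 ± 182 to 458 ± 73.6 normalized reads (SD, n = 3 per genotype), a log2 change of -1.38 ± 0.22 (SE, limma adjusted p = 0.00559). Every knockout library lay below every heterozygous library, but E2f1 reads remained in all 3 knockout libraries (375, 483 and 516), so the transcript was lower and not absent. E2f3 (ENSMUSG00000016477, chromosome 13, 29906575 to 29986063, minus strand) was at 250 ± 44.0 and 266 ± 50.1 normalized reads, a log2 difference of 0.09 ± 0.28 (adjusted p = 0.845). These values count reads over the whole gene, so transcripts from an allele that lacks only part of the gene can still be counted. The E2f3 value does not check recombination, and the source of the remaining E2f1 reads was not tested. Among the other E2F genes, E2f7 and E2f8, which encode repressors, fell 8.65-fold and 8.20-fold, and the activator E2f2 fell 6.89-fold. The dimer partner Tfdp1 had a log2 change of -1.14 ± 0.23 (adjusted p = 0.0141). E2f4, E2f5, E2f6 and Tfdp2 had log2 differences of -0.28, 0.15, -0.11 and -0.17 with adjusted p of 0.374 to 0.742. In this list of 10 genes 5 fell, both over all genes tested and adjusted over the list alone (camera adjusted p = 0.00451 with a preset correlation, adjusted p = 0.581 with an estimated correlation), and 3 fell without heterozygous B.

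**Figure D1:**
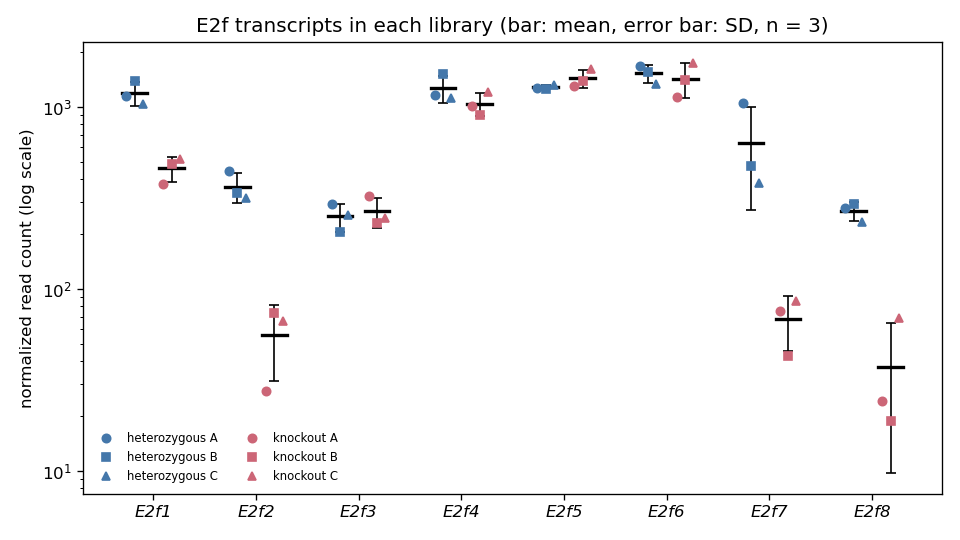
Normalized read counts (log axis) of 8 E2f genes in each of the 6 libraries, heterozygous in blue and knockout in red, with the mean and SD of the 3 libraries in black. E2f1 libraries sit at 1030 to 1388 in heterozygous and 375 to 516 in knockout cells, while E2f3 libraries overlap.

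Across the transcriptome 2883 of 18227 tested genes changed, 1318 higher and 1565 lower in knockout cells (limma, adjusted p under 0.05), a balance that reversed with upper-quartile scaling in edgeR (1572 higher, 1406 lower). Changes of at least 2-fold were found for 951 of the higher and 1138 of the lower genes. The smallest p-values among genes that fell belonged to Gad2, which encodes a GABA-synthesizing enzyme (11.6-fold, adjusted p = 0.000621), Sox11, a transcription factor of immature neurons (9.70-fold, 0.000621), and Stmn2, a neuronal microtubule regulator (8.06-fold, 0.000886). Among genes that rose they belonged to Lgals3, a galectin (3.47-fold, 0.00101), Creg2 (6.04-fold, 0.00101) and Hebp1 (3.60-fold, 0.00151). Among called genes with a mean of at least 50, a gene name and separated groups, the largest increases were those of Tnfsf10, which encodes the death ligand TRAIL, from 3.67 ± 3.06 to 109 ± 102 normalized reads, and Myof, from 8.03 ± 6.62 to 133 ± 84.4. Defb30, Pvalb, Exd1, Rgs22, Lama3 and Rab17 rose by 3.21, 2.96, 2.95, 2.92, 2.89 and 2.88 on the log2 scale. Tnfsf10, Myof, Defb30, Pvalb, Rgs22 and Lama3 stood highest in knockout A and lowest in knockout C (Pvalb at 1095, 589 and 208 in A, B and C). The ependymal and endothelial lists given below had the same order, whereas Exd1 and Rab17 did not. Within the same set the largest decrease was that of the histone gene H2ac11, from 304 ± 45.6 to 2.10 ± 1.98, a value that is uncertain because near-identical histone genes can share reads. AA387200 lies within 10 Mb of E2f1 and H2ac11 within 10 Mb of E2f3, and a local effect of the targeted alleles on either was not tested. Kcnb2, Zfp125, Kcnf1, Chodl, Fgf3, Krt73 and AA387200 had log2 changes of -5.21, -5.14, -4.91, -4.73, -4.33, -4.30 and -4.30, but Kcnf1 had 2 knockout libraries at 0, and its edgeR value was -2.82 (adjusted p = 0.180). The authors' deposited table gave -2.84 for Kcnf1 (adjusted p = 0.291). Groups did not overlap for 38.7% of tested genes, against 10% by chance. Without heterozygous A, heterozygous B or knockout B the count of changed genes was 906, 635 or 697, with no sign reversed among the 2883 genes. Knockout A had the highest levels of vessel and blood-cell markers, given below, and without it the count was 2230.

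Genes of the cell cycle fell together. Of 48 genes of mitosis and G2/M 46 fell and none rose, with a median log2 change of -2.59 (quartiles -2.82 and -2.29), including the proliferation marker Mki67 (10.8-fold, from 3450 ± 484 to 332 ± 111), Cenpa, the centromeric histone H3 variant (7.16-fold), and Ube2c, a ubiquitin-conjugating enzyme of anaphase (6.59-fold). Of 42 genes of DNA replication 28 fell (median -1.13), among them the kinase activator Dbf4 (3.72-fold) and the clamp loader genes Rfc3 (3.08-fold) and Rfc5 (2.56-fold). Of 24 genes of G1/S cyclins and nucleotide synthesis 18 fell (median -1.26), among them Tk1 (6.67-fold), Rrm2 (6.40-fold) and Ccne2, cyclin E2 (4.28-fold). Of 30 DNA repair genes 12 fell (median -0.86), with Brip1 at 6.41-fold, Rad51ap1 at 5.01-fold and Eme1 at 3.87-fold. Adjusted over the list alone, 47, 36, 21 and 18 members of these 4 lists fell. Among 16 pocket protein, kinase and inhibitor genes 7 fell and 1 rose (8 and 3 adjusted over the list alone). The inhibitor Cdkn2c (6.82-fold), Cdk1 (4.66-fold) and Ccnd2, cyclin D2 (3.26-fold) fell, whereas Ccnd1, cyclin D1, rose from 245 ± 55.1 to 556 ± 137. All 5 lists passed camera with a preset correlation (adjusted p from 4.97e-28 to 0.024) and each had an adjusted p = 0.581 with an estimated correlation. Counts for mitosis stayed between 36 and 46 when any 1 library was left out, but the replication count was 7, 3 and 5 without heterozygous A, heterozygous B and knockout B. The DNA repair count was 4, 1 and 5, and the G1/S count 10, 9 and 9, without the same 3 libraries, and 4 pocket protein and kinase genes fell without knockout B. Ccnd1 was not called without any of these 3, and 2 genes of its list rose without knockout A.

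Markers of cell state along the neurogenic lineage moved in opposite directions. Of 34 neuroblast genes 33 fell, both over all genes and adjusted over the list alone (median -2.79, a 6.93-fold decrease), with every knockout library below every heterozygous library. Of 27 genes marking activated stem cells and transit-amplifying progenitors 15 fell and 1 rose (15 and 1 adjusted over the list alone, median -0.84). Of these 27 genes 10 are also on other lists, such as Sox11 (neuroblast) and Ccnd2 (cell cycle), so the lists are not independent. Sox4 fell 5.88-fold and the non-coding RNA Lockd 10.4-fold, and Rgcc was the member that rose. The growth factor receptor gene Egfr, singled out after its values were seen, had a log2 difference of 0.27 ± 0.33 (adjusted p = 0.603). Of 40 markers of quiescent stem cells and astrocytes 8 rose and none fell (16 adjusted over the list alone; median 0.70), and 39 had a positive fold change. A positive median was not particular to this list. Among the lists of other cell types, given below, only striatal and mature neuron genes had a negative median (-1.77). The intermediate filament gene Gfap rose from 5192 ± 304 to 11269 ± 2451 normalized reads (2.14-fold), Id3, an inhibitor of differentiation, 2.54-fold, and Fxyd1 1.85-fold. Camera adjusted p-values with a preset correlation were 2.63e-24, 5.50e-05 and 4.76e-07 for the neuroblast, activated and quiescent lists, and each had an adjusted p = 0.581 with an estimated correlation. The unadjusted camera p with an estimated correlation was 0.0523, 0.172 and 0.243 in the same order. The neuroblast and activated lists passed fry (adjusted p = 0.0202 and 0.0474), and the quiescent list did not (0.105). The quiescent count was 1, 0, 21 and 1 without heterozygous A, heterozygous B, knockout A and knockout B, the activated count was 9 without heterozygous B, Rgcc was not called without heterozygous A, heterozygous B or knockout B, and the neuroblast count stayed between 29 and 33.

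**Figure D2:**
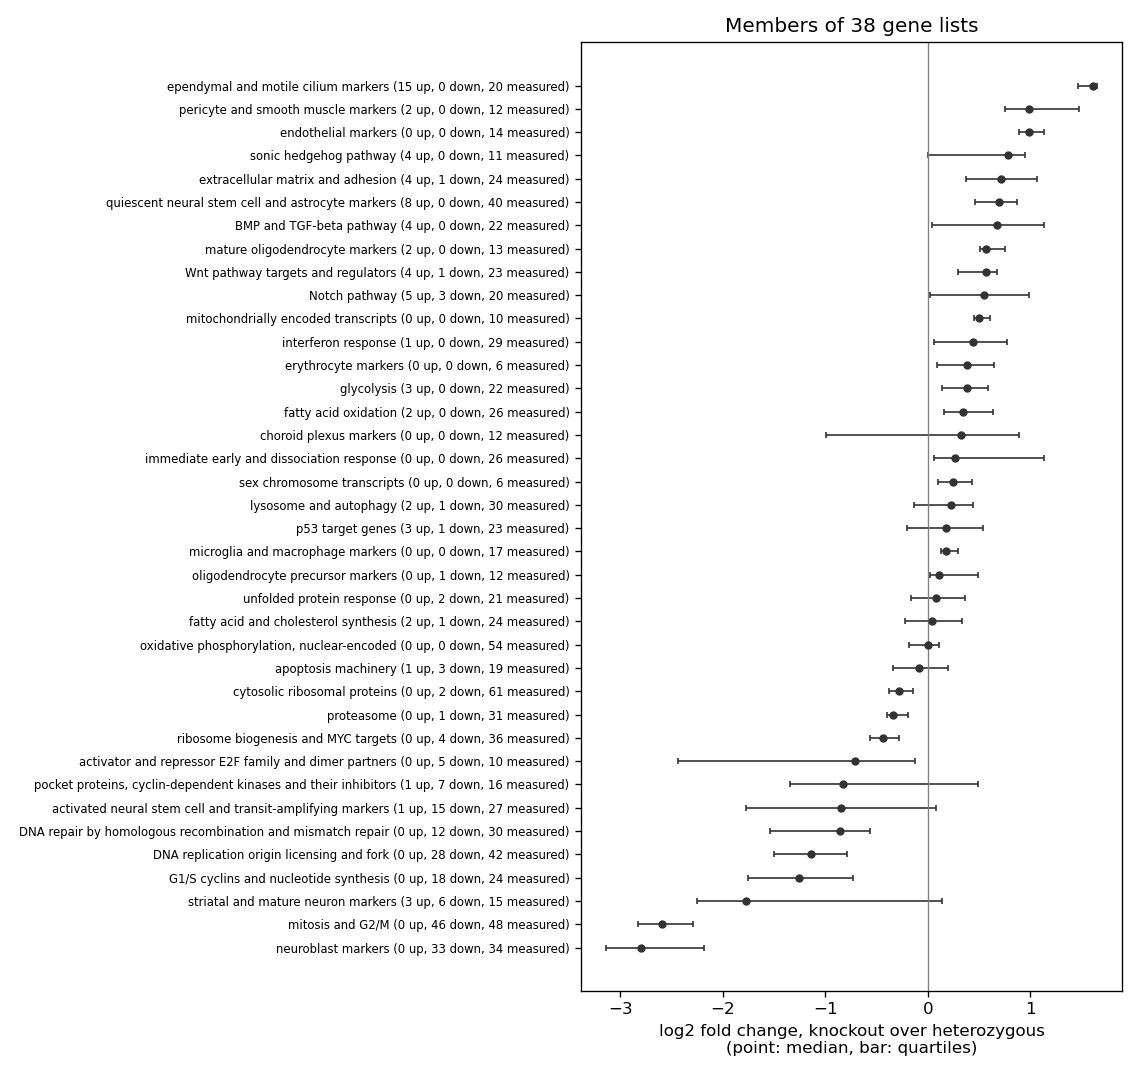
Median log2 fold change (knockout over heterozygous, n = 3 libraries each) of the measured members of 38 gene lists, with bars from the lower to the upper quartile and the numbers of members past the limma threshold in brackets. Neuroblast and mitosis genes lie lowest at -2.79 and -2.59, and ependymal genes highest at 1.62.

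Several signalling lists shifted upward, but only the BMP and TGF-beta list had every knockout library above every heterozygous library in mean level. Heterozygous C (0.21 and 0.22) lay above knockout A (0.16 and 0.03) for the hedgehog and Wnt lists. For the Notch list it lay above knockout B (0.224 and 0.204). In the BMP and TGF-beta list 4 of 22 genes rose (9 higher and 1 lower adjusted over the list alone, median 0.68), including the ligand Bmp6 (3.84-fold) and its antagonist Nog (3.17-fold). Other lists share 5 members of the BMP list, among them Id3, given above with the quiescent markers. In the sonic hedgehog list 4 of 11 rose (5 adjusted over the list alone; median 0.78), including Boc (2.01-fold), Smo (1.72-fold) and the receptor Ptch1 (1.85-fold). In the Wnt list 4 of 23 rose and 1 fell (the same numbers adjusted over the list alone; median 0.56), and Tcf7l1 (1.88-fold) and the secreted inhibitors Sfrp5 (2.07-fold) and Notum (2.14-fold) were among those that rose. In the Notch list 5 of 20 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0954). Hey1, a Notch effector, rose 2.31-fold, while Mfng and the ligand Dll3, both also on the activated stem cell list, fell 3.94-fold and 3.19-fold. Camera adjusted p-values with a preset correlation were 0.00775, 0.0304 and 0.0212 for the BMP, hedgehog and Wnt lists, and 0.581, 0.668 and 0.603 with an estimated correlation. Without heterozygous A, heterozygous B or knockout B no hedgehog or Wnt gene rose, 1 Notch gene rose in each case, and 1, 1 and 2 BMP genes rose. In the same cases 1, 0 and 1 Notch genes fell, and the Wnt gene that fell was not called without heterozygous B, knockout A or knockout B. Without knockout C the numbers that rose were 7 for BMP (1 fell), 1 for hedgehog, 2 for Wnt and 3 for Notch, and without heterozygous C 2 Wnt genes rose. The hedgehog list lost its camera call without heterozygous B (adjusted p = 0.0624), knockout B (0.0707) or knockout C (0.168), and the Wnt list without heterozygous A (0.0704) or knockout C (0.163).

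Growth and metabolism lists moved less. Of 36 ribosome biogenesis and MYC target genes 4 fell (4 adjusted over the list alone; median -0.44), with Mycl at 5.26-fold, Eif4a1 at 2.00-fold and Nop56 at 1.79-fold. Of 61 cytosolic ribosomal protein genes 2 fell, among them Rps2 (1.58-fold), and of 31 proteasome genes 1 fell, Psmc6 (1.58-fold), with none adjusted over the list alone. In fatty acid oxidation 2 of 26 genes rose, Acaa2 and Eci1 (none adjusted over the list alone), and in glycolysis 3 of 22 rose (5 adjusted over the list alone), including the glucose transporter gene Slc2a1 (2.12-fold), the lactate transporter gene Slc16a1 (1.92-fold) and Aldoa (1.70-fold). These 5 lists passed camera with a preset correlation (adjusted p from 5.50e-05 to 0.0141), and with an estimated correlation had adjusted p = 0.581, 0.777, 0.674, 0.668 and 0.581 in the order given. Of 24 genes of lipid synthesis 2 rose, Scd1 and Srebf1, and 1 fell (2 higher, none lower adjusted over the list alone). Of 30 lysosome and autophagy genes 2 rose, Tfeb and Ctsl, and Atp6v1h fell (1 higher adjusted over the list alone). None of 54 nuclear-encoded respiratory chain genes passed limma or edgeR, and 0 had an unadjusted p under 0.05 (smallest p for Cox7a2, log2 difference -0.43). Of 10 mitochondrially encoded transcripts 0 passed either tool and 1 had an unadjusted p under 0.05 (mt-Nd5, log2 difference 0.67). Camera gave adjusted p of 0.0871 to 0.833 for these last 4 lists. No gene of fatty acid oxidation, the ribosomal protein list or the proteasome was called without heterozygous A, B or C or knockout B, and none of glycolysis without heterozygous B or knockout B. Without heterozygous A, heterozygous B or knockout B 1 gene of ribosome biogenesis fell, 1 of lipid synthesis rose and no lysosome gene was called. Without knockout A 6 genes of fatty acid oxidation and 5 of glycolysis rose, 4 ribosomal protein genes fell and no lysosome gene fell. Without knockout C 1 gene each of fatty acid oxidation, lipid synthesis and the lysosome list rose, no ribosomal protein gene, 4 proteasome and 3 lipid synthesis genes fell, and the lipid synthesis gene that fell was not called without any other library. The fatty acid oxidation list lost its camera call without knockout C (adjusted p = 0.157).

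Stress-related lists held 0 to 4 calls each. The share called was above the 15.8% of all tested genes for p53 target and apoptosis genes. It was below that for the unfolded protein response, interferon and immediate early lists. Among 23 p53 target genes 3 rose and 1 fell, with the same numbers adjusted over the list alone: Perp and Polk rose 2.22-fold and 1.81-fold, and Psrc1, which acts at the mitotic spindle, fell 5.45-fold. Among 19 apoptosis genes 3 fell and 1 rose (3 and 2 adjusted over the list alone), with Apaf1 3.08-fold lower and Trp73 4.57-fold higher. Trp73 stood at 980, 865 and 344 normalized reads in knockout A, B and C, the order of the ependymal list given below. Of 21 genes of the unfolded protein response 2 fell, Asns (4.88-fold) and Chac1 (5.10-fold), also adjusted over the list alone. Of 29 interferon response genes 1 rose, H2-K1 (1.78-fold; none adjusted over the list alone). Of 26 immediate early genes 0 passed limma or edgeR and 2 had an unadjusted p under 0.05 (Egr1, log2 difference -1.12 ± 0.44, adjusted p = 0.109). Camera gave adjusted p of 0.137 to 0.868 for these 5 lists. No p53 target rose without heterozygous A, heterozygous B or knockout B, and 1 gene of the unfolded protein response fell in each case. Without heterozygous C 1 p53 target, 2 apoptosis genes and 3 immediate early genes rose, and without knockout A 1 p53 target rose. No apoptosis gene rose without heterozygous B or knockout B. H2-K1 was not called without heterozygous A, heterozygous B, knockout A or knockout B. Without knockout C 3 interferon genes and 2 immediate early genes rose and 1 of each fell.

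Markers of other cells of the ventricular wall varied between libraries. Of 20 ependymal and motile cilium genes 15 rose (20 adjusted over the list alone; median 1.62), and those with the smallest p-values were Foxj1, the regulator of motile cilia, from 800 ± 93.8 to 3596 ± 1790 normalized reads (4.08-fold), Rsph4a (3.14-fold) and Tppp3 (2.82-fold). Relative to the heterozygous mean this list stood at 2.39, 1.85 and 0.48 in knockout A, B and C. Endothelial genes stood at 2.47, 1.09 and -0.47 in the same libraries, and 0 of 14 passed limma or edgeR, with 2 at an unadjusted p under 0.05 (Cldn5, 659 ± 81.2 and 2457 ± 2464 normalized reads). Pericyte and smooth muscle genes stood at 1.86, 1.36 and 0.13, and 2 of 12 rose, Notch3, which is also on the Notch list, and Pdgfrb (4 adjusted over the list alone). Of 13 mature oligodendrocyte genes 2 rose, Aspa and Ermn (2 adjusted over the list alone). Of 24 extracellular matrix genes 4 rose and 1 fell (the same numbers adjusted over the list alone), including Col1a1 (5.38-fold) and Sparc (2.17-fold) among the higher and Vcan (2.79-fold) as the lower gene. Camera adjusted p-values with a preset correlation were 4.43e-07, 0.024, 0.00451, 0.00224 and 0.0212 for these lists in that order, and 0.581, 0.777, 0.603, 0.581 and 0.581 with an estimated correlation. The ependymal count was 2, 0, 4, 6 and 1 without heterozygous A, B, C, knockout A and knockout B, and the endothelial list lost its camera call without knockout A (adjusted p = 0.314) or heterozygous C (0.052), and the matrix list without heterozygous B (0.0619). Without knockout C 14 endothelial, 8 pericyte and 7 extracellular matrix genes rose, and without heterozygous A, heterozygous B or knockout B 1 matrix gene and no pericyte or mature oligodendrocyte gene rose. Mature oligodendrocyte calls were 1 without heterozygous C and 0 without knockout A, and Vcan was not called without heterozygous A or knockout B, while 2 matrix genes fell without knockout C.

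The remaining cell type lists did not pass camera (adjusted p of 0.0638 to 0.874). Of 15 striatal and mature neuron genes 6 fell and 3 rose (7 and 3 adjusted over the list alone), with Snap25 and Syt1, both of the synaptic vesicle release machinery, 5.90-fold and 3.84-fold lower and Ppp1r1b 2.06-fold higher. Of 12 oligodendrocyte precursor genes 1 fell, Cacng4 (none adjusted over the list alone), and the list stood at 1.72 in heterozygous C and 1.19 in knockout C against -1.02 to -0.19 in the other libraries. Microglia genes stood highest in knockout A (2.07) and next in heterozygous C, and erythrocyte genes in knockout A (2.41). Choroid plexus genes stood highest in heterozygous A (3.40). None of the 17 microglia, 6 erythrocyte and 6 sex chromosome genes passed limma or edgeR or had an unadjusted p under 0.05, and Ddx3y was at a log2 difference of 0.49. Of 12 choroid plexus genes 0 passed limma, 1 passed edgeR and 2 had an unadjusted p under 0.05 (Calml4, log2 difference 1.71 ± 0.62, limma adjusted p = 0.0895). Without heterozygous A, heterozygous B or knockout B 1 striatal neuron gene fell, and 1, 1 and 0 rose. Cacng4 was called only with all libraries or without knockout C, and 2 oligodendrocyte precursor genes rose without heterozygous C. Without knockout C 2 choroid plexus and 3 erythrocyte genes rose, and without heterozygous A 1 choroid plexus gene rose.

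**Figure D3:**
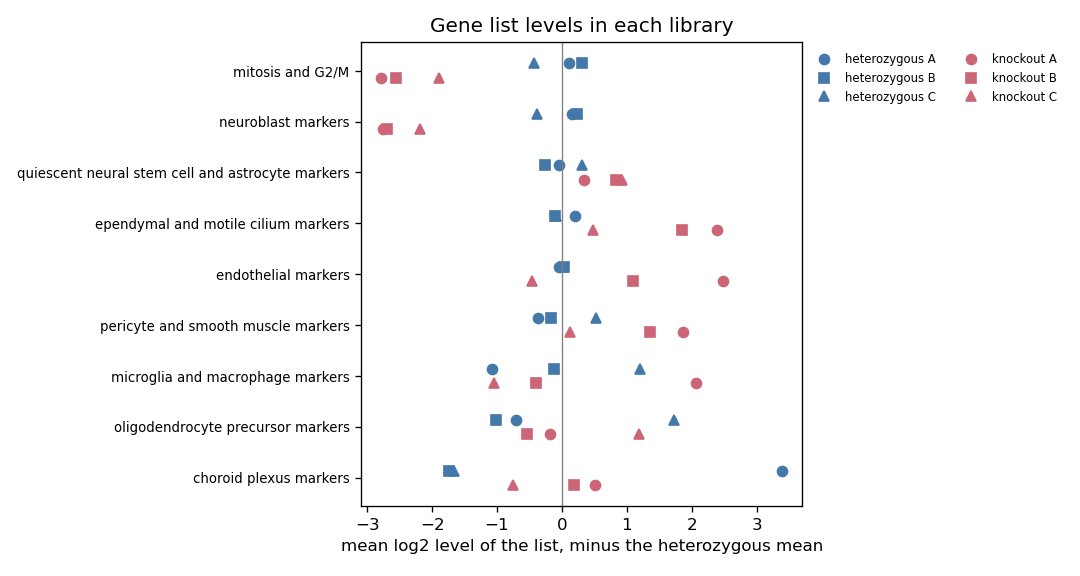
Mean log2 level of 9 gene lists in each library, minus the mean of the 3 heterozygous libraries, with heterozygous libraries in blue and knockout libraries in red. Mitosis and neuroblast levels lie at -1.89 or lower in all 3 knockout libraries, while endothelial levels range from -0.47 to 2.47 among them.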

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

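These 5 alternatives were chosen after seeing the data: edgeR with TMM, limma without a variance trend, limma on TMM-rescaled reads, limma with a replicate block, and camera on limma-voom values with TMM. E2f1 stayed past the threshold in all 24 settings (log2 change -1.48 to -1.24) and E2f3 in none (-0.06 to 0.21). E2f3 changed sign without heterozygous B (-0.0461) and without knockout A (-0.0581), far from the threshold both times, and the cause was not tested. Changed genes numbered 2883 (1318 higher, 1565 lower) and no gene among them reversed sign in any alternative. For the 2866 of them with separated groups, leaving out 1 library could not have reversed the sign. Changed genes numbered 1036 (317 and 719) without a variance trend, 4452 (2318 higher) with DESeq2, 4514 (2354 higher) by the authors' adjusted p, 618 (115 and 503) at 0.01 and 4757 (2348 and 2409) at 0.1. The cause was not tested except for the thresholds, whose construction sets the count. With 1 library left out, changed genes ranged from 635 to 4019, higher genes from 109 to 1956 and lower genes from 469 to 2063, with fewer samples in the fit. The letters A, B and C did not pair the libraries: same-letter deviations correlated at -0.07, 0.02 and -0.10. A replicate block gave 1604 genes in edgeR (711 higher, 893 lower) and 2310 in limma. The excess of lower over higher genes depended on the setting: upper-quartile scaling gave 1572 higher and 1406 lower (median log2 change of tested genes 0.13 in place of 0.05), the filter of 10 CPM in 3 libraries 1623 and 1453, and DESeq2 and the authors' adjusted p 2134 and 2160 lower. Lists past the threshold numbered 22, against 0 with an estimated correlation, which asks the same question, and 6 with fry, which asks another, and 20 to 26 with 1 library left out. In the simulation limma called 92 genes and recovered 14% of 2-fold changes. With 2883 calls in the real data the same adjusted threshold admits larger unadjusted p-values. The 14% therefore does not give the recovery in the real comparison, which was not measured. Genes not called may still differ 2-fold.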

Other observations

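All tests in this part were chosen after the data were seen, except those on chance splits of the gene count, loci beside E2f1 and E2f3, gene length and GC content, and the 5 lists of other cell types. Gene families defined by a shared symbol stem, with at least 8 tested members, were tested for an excess of calls (Fisher's exact test, one-sided, adjusted over 273 families in both directions). Axonemal and ciliary genes stood out upward: 20 of 32 Cfap genes (median log2 change 1.52, adjusted p = 3.10e-12) and 8 of 14 dynein heavy chain genes (Dnah, 1.51, adjusted p = 0.000368) rose and none fell, with 2 members of each family also on the fixed lists. Coiled-coil Ccdc genes rose in 32 of 116 cases and fell in 7, and leucine-rich repeat Lrrc genes rose in 13 of 50 and fell in 4. The Fisher test treats genes as independent, whereas the ependymal list had an estimated inter-gene correlation of 0.930 and an adjusted p = 0.581 at that correlation. Relative to the heterozygous mean, Cfap genes stood at 2.08, 1.72 and 0.56 and Dnah genes at 2.27, 1.45 and 0.41 in knockout A, B and C, against 2.39, 1.85 and 0.48 for the ependymal list. With heterozygous A, B, C, knockout A, B or C left out, 6, 0, 7, 9, 0 and 31 Cfap genes, 1, 0, 4, 3, 0 and 13 Dnah genes, 6, 2, 15, 14, 3 and 42 Ccdc genes and 1, 0, 4, 7, 0 and 15 Lrrc genes rose. In the same order 1, 1, 4, 5, 1 and 10 Ccdc genes and 1, 1, 3, 4, 1 and 4 Lrrc genes fell. Of 10 Dlx-stem and 10 Mcm-stem genes 7 and 6 fell, with 5 and 7 of the 10 on the fixed lists. These stems also take in the antisense or opposite-strand transcripts Dlx1as, Dlx6os1 and Dlx6os2 and the gene Mcm3ap, all of which fell. The number of Dlx-stem genes that fell was 7 with any library left out, with 2 others rising without knockout C. The Mcm-stem count was 0 without heterozygous A, heterozygous B or knockout B. Annexins, which bind membranes in a calcium-dependent way, rose in 5 of 10 cases (adjusted p = 0.0348), including Anxa2 (log2 change 1.27) and Anxa5 (1.16). The family stood at 1.65, 1.22 and 0.29 in knockout A, B and C, the same order of libraries as for the ependymal, endothelial and pericyte lists, and 1, 0 and 0 rose without heterozygous A, heterozygous B and knockout B and 9 without knockout C. Downward, 8 of 21 Nup-stem genes, most of them nucleoporins, fell (adjusted p = 0.0348), with Nup107 at -1.72 and Nup62 at -1.46, and 2, 1, 5 and 2 fell without heterozygous A, heterozygous B, knockout A and knockout B. Kinesin-stem genes were split: 16 of 35 fell, 7 of the 35 being on the lists, while Kif6, Kif9 and Kif27 were among the 4 that rose; 10 fell without heterozygous B, and 2, 0 and 0 rose without heterozygous A, heterozygous B and knockout B.

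The ribosomal protein gene Rpl29, on none of the lists, fell from 772 ± 125 to 78.4 ± 11.9 normalized reads (log2 change -3.28 ± 0.27, limma adjusted p = 0.000886), whereas the 61 listed ribosomal protein genes had a median of -0.28. The source of this fall, including strain differences or reads shared with similar sequences, was not tested.

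The number of changed genes was weighed first. The real split called 2883 genes, and the highest of the other 9 splits of the 6 libraries into 3 and 3 called 0 in limma and 0 in edgeR (61 to 1342 genes at an unadjusted p under 0.05); with 10 splits, 1 of which reached the real count, no share under 0.05 is possible. For gene lists the real split put 22 past the threshold with a preset correlation, while the highest other split, heterozygous A and B with knockout A against the rest, put 23 past it, so 2 of 10 splits reached the real count. Each other split mixes the genotypes as 2 libraries and 1, so part of the genotype difference stays in it. This remainder, a sample structure beyond genotype or a preset correlation that is too low for these lists could give such counts. No test separated these. The splits therefore cannot decide whether the list calls with a preset correlation reflect genotype.

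Strain-derived segments carried along with the E2f1 and E2f3 alleles may change nearby genes. Within 10 Mb 67 of 350 tested genes (19.1%) were called, against 2813 of 17860 (15.8%) elsewhere. The odds ratio was 1.27 (95% interval 0.952 to 1.66, Fisher's exact test, two-sided, p = 0.0888), so an excess near the loci is not excluded. Most calls lay outside these windows, which argues against local effects of such segments as the general source. Strain differences elsewhere on the mixed background were not tested. For single genes within these 10 Mb, among them AA387200, H2ac11 and Sox4, this test does not decide. Fold changes followed gene length and GC content weakly across genes (Spearman rho -0.08 and 0.11, genes not being independent replicates). The GC value lay just above the 0.1 set beforehand for ruling out such a bias, but 3252 genes were called once both trends were removed per library, 2639 of them among the 2883, which argues against it as the main source. A different share of other cell types stays open for the genes that rose: of 5 lists of such cells, 5 had a median above 0. However, microglia genes stood at 2.07, -0.40 and -1.04 and endothelial genes at 2.47, 1.09 and -0.47 in knockout A, B and C. The reporter sort should exclude unmarked cells, yet 17 of 18 listed microglia genes had a mean of at least 10. As the whole source of the fall in mitosis and neuroblast genes, dilution by cells lacking quiescent stem cell and astrocyte markers is argued against. Such dilution would lower that list too, but the list stood 0.70 higher on the log2 scale, with the genotypes separated. Added cells that express these markers, such as astrocytes, would raise the list, so this comparison cannot address them. A loss of cycling cells and neuroblasts, or lower transcription within them, cannot be resolved in sorted pools and was not tested. Effects of E2f1 loss before tamoxifen, including during development, also cannot be told apart from those of E2f3 loss after it.

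The rise of ependymal genes may reflect fewer neuroblasts in the sort, since that raises all other cell types alike. The knockout minus heterozygous difference was 0.88 ± 0.75 (SE) larger for the ependymal list than for the quiescent list on the log2 scale (exact permutation test, two-sided, p = 0.400, smallest possible 0.1), so this explanation cannot be told apart from a change in ependymal cells with 3 libraries per genotype. Carry-over of cells from around the ventricle is also open. The sort on the Nestin-Cre reporter should exclude unmarked cells, but 17 of 18 listed microglia and 6 of 8 erythrocyte genes had a mean of at least 10. Those lists stood highest in knockout A, at 2.07 and 2.41. Whether unmarked cells passed the sort was not tested. Without knockout A 6 of 15 ependymal genes were still called, with a median of 1.13 in place of 1.62, and without knockout C all 20 measured genes were called with a median of 2.15.

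In total 26 genes were nearly on or off by genotype, each library of 1 genotype being over 10 times every library of the other: 11 were on in knockout and 15 in heterozygous cells. They include H2ac11 and Zfp125, given above, and the sodium channel gene Scn1a (62.1 ± 5.08 and 2.77 ± 1.76 normalized reads in heterozygous and knockout cells). Strain-derived segments may account for some. Of the 26, 4 lay within 1 Mb of another, against a median of 0 and a 95th percentile of 4 in 10000 random sets matched on mean value (permutation test, one-sided, p = 0.065). Those 4 are 2 pairs, and the annotations of Zfp125 and 3110053B16Rik overlap, so they can share reads. Only 1 of the 26, H2ac11, lay within 10 Mb of E2f1 or E2f3, and the question stays open.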
